A study of Danaus plexippus with 36 samples.

How the data were processed

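The study measured gene expression in the antennae, the legs and the proboscis of adult monarch butterflies (Danaus plexippus). Per the labels, the animals were caught in the field, sexed and dissected, and the females were gravid. RNA was sequenced from 6 females and 6 males, numbered by animal, in 2 batches that each held 3 females and 3 males. Messenger RNA libraries were prepared from 100 ng of total RNA with a strand-specific Illumina kit, per the labels' protocols.

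The deposited values are raw read counts per gene, with 15130 rows named by gene model identifiers that begin with DPOGS. Per the submitters' processing notes, the tools behind these deposited counts include FastQC 0.11.5, HISAT2 2.0.5, featureCounts 1.5.2 and limma. The genome build, the annotation release, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Genes that share reads with a near-identical copy, or that overlap a gene on the other strand, are therefore uncertain in these counts. The values were whole numbers that summed to different totals, so they were treated as counts with no scaling by the authors. Of the 36 samples in the labels 35 were analysed, since the counts used here held no values for the antennae of male 2. Male antennae had 5 libraries and each other combination of sex and tissue had 6.

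The identifiers matched 0 entries of the gene name table that was used (assembly MEX_DaPlex), and the deposited table does not pair them with names. Gene families could not be looked up, so the lists of chemosensory receptors, cell type markers and other families fixed before the data were examined were void. Ranked within each comparison, at most 2 genes that were higher and 2 that were lower are named by identifier, without a location. The rule for naming was also fixed before the data were examined. For tissue comparisons it took the largest fitted changes among genes with an adjusted p below 0.05, the same direction in every animal with both tissues (11 animals for comparisons with antennae, 12 for legs against proboscis) and a mean of at least 10 CPM (counts scaled to a library total of 1000000) in the higher tissue. For sex comparisons it took the largest fitted changes with a mean of at least 1 CPM in the higher sex.

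Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr over the 6 groups of sex and tissue, which left 11804 genes and removed 3326 rows that together held 0.0391% of all counts, 516 of them without a count in any library. Libraries were scaled by the trimmed mean of M values (TMM). The tissue comparisons and the sex by tissue interaction came from 1 quasi-likelihood fit of the 35 libraries with group means and batch as terms. The sex and batch comparisons came from the libraries of each tissue alone, with sex and batch as terms and TMM factors computed within the tissue. P-values were adjusted with the Benjamini-Hochberg method over the genes tested in each comparison, and a gene was called at an adjusted p below 0.05. Fold changes are fitted log2 values with a standard error derived from the quasi-likelihood F statistic. Mean CPM values use TMM-scaled library sizes and are given with the SD over libraries. The number of genes with a count was compared between libraries as the number expected in a random draw of 600000 counts. Within-animal differences in library measures were tested with an exact sign-flip permutation test, 2-sided, with Benjamini-Hochberg adjustment over 6 tests. Figures were drawn with matplotlib 3.10.9.

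A fold change against a group without a count is given as a lower bound, computed against a floor of 3 counts over the whole group. Where the lower group held 1 to 3 counts, the ratio of summed counts is given with its exact (Clopper-Pearson) 95% interval. These bounds and intervals cover counting error only, since reads copied in the library preparation are not independent molecules.

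The animal number was shared between tissues because the tissues came from the same animals, so the libraries are paired by animal. Deviations from the group means of libraries of the same animal had a median correlation across genes of 0.106 between antennae and legs (6 of 11 animals above 0.1), 0.214 between antennae and proboscis (11 of 11) and 0.462 between legs and proboscis (10 of 12). These deviations still held the batch difference. Taken from the means of each group and batch, the medians were 0.158 (8 of 11), 0.189 (9 of 11) and 0.33 (10 of 12), in the same order. As fixed beforehand, the main fit had no term for the animal, and a fit with the animal as a block was an alternative. No 2 libraries of a group agreed within sampling noise, the smallest chi-square per gene between 2 libraries of a group being 26.4, so each library was counted as 1 replicate. The p-values of the sex and batch comparisons within a tissue measure the spread between animals. Those of the tissue comparisons and the interaction measure the spread between libraries within the groups and leave out the pairing.

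The scripts were tested on simulated counts that had the means, library sizes and spread of the real libraries, with 200 genes changed by known factors, 50 at each of 4 sizes. Between antennae and legs 60% of 4-fold changes were recovered (11804 genes), between antennae and proboscis 76% (11804 genes) and between legs and proboscis 46% (11804 genes). For the sex comparisons the shares at 4-fold were 18% in antennae (11746 genes), 74% in legs (11794 genes) and 32% in proboscis (11794 genes). False calls made up 1.09% to 3.85% of the calls in the simulated comparisons. The simulated libraries were drawn independently, without the pairing by animal or a batch difference that depended on the tissue. These shares therefore do not cover errors from either.

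The alternatives were DESeq2 size factors and upper-quartile scaling, no filter and a stricter filter (at least 1 CPM in at least 6 libraries), DESeq2 1.42.0 and limma 3.58.1 (voom, with and without sample quality weights) as tests, no batch term, the animal as a block or as a random effect, each batch alone, each sex alone, all libraries in 1 fit for the sex comparisons, and leaving out each animal in turn. After the data were seen, fits were added without the 4 libraries under 3 M counts, for the tissue comparisons without the 2 libraries under 2 M counts (1 antennal and 1 proboscis), with libraries thinned to 2 M counts (without these 2, and with the low-count filter applied anew), without the 10 libraries of batch 2 over 24 M counts (1 antennal, 6 leg and 3 proboscis), with 1 surrogate variable (sva 3.50.0), and with a batch term for each tissue.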

Results

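Antennae, legs and proboscis are the appendages with which a butterfly smells and tastes, and the study compared their transcriptomes between tissues and between the sexes with a focus on chemosensory genes. The libraries held 11 antennal, 12 leg and 12 proboscis samples from 12 animals. Total counts per library, in units of 1000000 counts (M), ran from 0.622 to 24.7 M in antennae (median 5.50 M), from 11.7 to 117 M in legs (median 25.4 M) and from 1.92 to 53.7 M in proboscis (median 13.2 M). The libraries of batch 1 lay between 3.68 and 15.2 M counts and those of batch 2 between 0.622 and 117 M. The leg libraries of batch 2, at 35.6 M or more, were all deeper than those of batch 1, at 15.2 M or fewer.

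The first principal component of the log2 CPM values held 30.2% of the variance and varied with the tissue and, in legs, with the batch. It had a mean score of -127 ± 27.8 (SD, n = 11) in antennae, 91.0 ± 37.8 (SD, n = 12) in legs and 25.8 ± 38.0 (SD, n = 12) in proboscis. In batch 1 and batch 2 the mean scores were 57.6 ± 6.49 and 124 ± 20.5 in legs, 15.5 ± 11.2 and 36.1 ± 52.9 in proboscis (SD, n = 6 each), and -122 and -134 in antennae. Of the 35 libraries, 33 correlated best with a library of their own tissue. The median correlation across genes was 0.853 between 2 libraries of the same tissue and 0.718 between libraries of different tissues. Within a tissue it was 0.779 in antennae, 0.9005 in legs and 0.862 in proboscis. Antennal transcriptomes were spread more evenly over genes: the 10 most abundant genes took 13.6% ± 1.77 (SD, n = 11) of the counts in antennae, 21.7% ± 3.93 (SD, n = 12) in legs and 19.5% ± 4.37 (SD, n = 12) in proboscis. The share was lower in the antennae than in the legs of 11 of 11 animals, and likewise than in the proboscis of 11 of 11 animals (exact sign-flip permutation test, p = 0.000977, the smallest these 11 animals can give, adjusted p = 0.00293 in both). Within batch 1 the shares averaged 12.5% in antennae, 23.4% in legs and 19.04% in proboscis, and within batch 2 14.8%, 20.0% and 19.9%. The share was higher in legs than in proboscis in 10 of 12 animals, a difference that did not pass (mean difference 2.24 ± 5.18 percentage points, SD, n = 12, exact permutation p = 0.165, adjusted p = 0.248). In a draw of 600000 counts, legs showed 9354 ± 289 genes (SD, n = 12) and proboscis 9757 ± 490 (SD, n = 12), fewer in legs in 11 of 12 animals (exact permutation p = 0.00781, adjusted p = 0.0156). The order held within batch 1 (9461 in legs and 9906 in proboscis) and within batch 2 (9247 and 9609). Antennae, with 9704 ± 853 genes (SD, n = 11), were not separated from legs (adjusted p = 0.252) or proboscis (adjusted p = 0.747) by the same exact test. The antennal libraries were uneven: those of female 18, female 11, male 12 and male 20 showed 8582 to 8781 genes, and the others 9582 or more. Those 4 animals had fewer genes in antennae than in legs, and the other 7 had more.

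**Figure D1:**
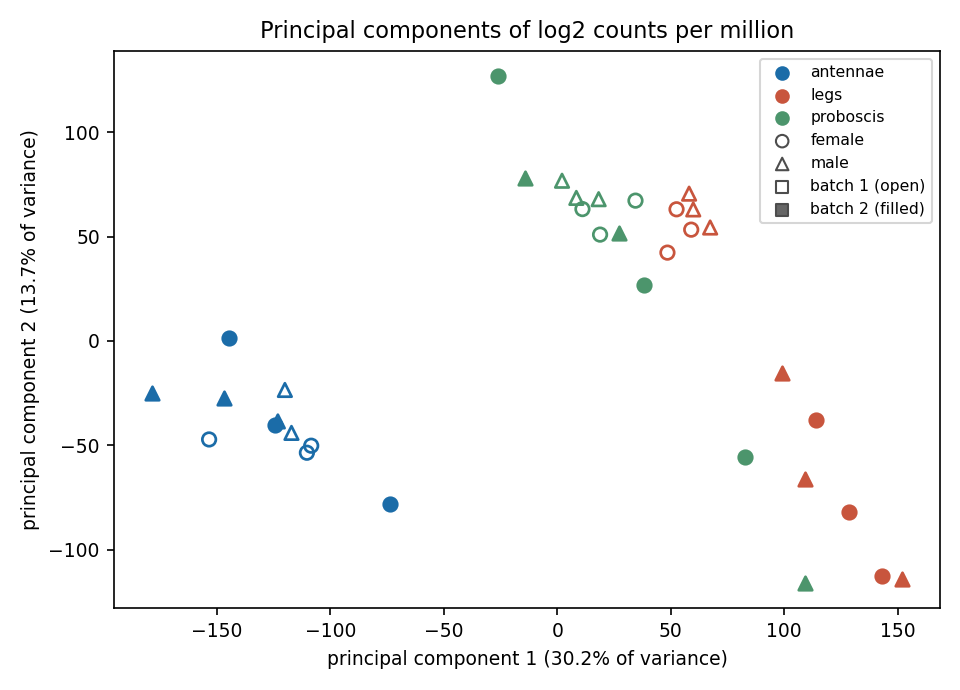
Each point is 1 library, placed by its scores on principal components 1 (30.2% of variance) and 2 (13.7% of variance) of log2 CPM; colour gives the tissue, circles are females and triangles males, open symbols are batch 1 and filled symbols batch 2. Antennae lie apart at the left, while the filled leg symbols and some filled proboscis symbols lie away from the open symbols of their tissue.

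Antennae and legs had the most genes that differed. Of 11804 genes tested, 2979 were higher and 3102 lower in antennae than in legs (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). The split moved both ways with the setting: upper-quartile scaling gave 3478 higher and 2551 lower genes (57.7% higher instead of 49.0%) and DESeq2 size factors 3240 and 2856, while the animal as a block gave 2610 and 3378 (43.6%), limma voom 2670 and 3469 and limma with the animal as a random block 2881 and 3768. Without the 2 libraries under 2 M counts 2678 were higher and 3458 lower (43.6%), and with the others thinned to 2 M counts and filtered anew 2995 were higher and 2292 lower (56.7%). At least 2-fold differences were found for 2539 of the higher and 2391 of the lower genes, and differences of at least 32-fold for 256 and 324. The gene DPOGS212737 averaged 3258 ± 2823 CPM (SD, n = 11) in antennae and 0.296 ± 0.492 CPM (SD, n = 12) in legs, a log2 fold change of 13.63 ± 1.08 (SE, adjusted p = 3.65e-12), and every antennal library lay above every leg library. The legs of male 12 held 198 of its 244 leg counts, and the leg mean was 0.159 CPM without them. DPOGS203667 averaged 366 ± 528 CPM in antennae and 0.0568 ± 0.178 CPM in legs, with a log2 fold change of 13.30 ± 1.03 (SE, adjusted p = 2.02e-11). Its counts in legs came from 2 of the 12 libraries, 68 of 70 from male 12, and without that library the leg mean was 0.00567 CPM. The log2 fold change was 15.7 without male 12, 14.1 without female 3 and 12.3 without male 16. In the other direction, DPOGS207541 had no count in any of the 11 antennal libraries and 1320 ± 1619 CPM (SD, n = 12) in legs, at least 13600-fold lower in antennae (adjusted p = 6.70e-06). DPOGS207153 also had 0 counts in antennae and 269 ± 306 CPM in legs, at least 2883-fold lower in antennae (adjusted p = 9.49e-06). Leg levels of the last 2 genes differed between batches: DPOGS207541 averaged 2638 ± 1263 CPM (SD, n = 6) in batch 1 and 1.72 ± 1.00 CPM (SD, n = 6) in batch 2, and DPOGS207153 averaged 535 ± 189 and 2.38 ± 2.80 CPM (1.39 CPM in batch 2 without female 1). Computed on the leg libraries of batch 2 alone, the bounds were 48.7-fold and 76.2-fold. For DPOGS207153 the legs of female 1 held 415 of the 723 counts behind this bound. Within batch 2 alone neither gene passed the threshold between antennae and legs (adjusted p = 0.0617 and 0.0548).

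The comparison called 4480 genes in batch 1 alone and 5593 in batch 2 alone. Of 2883 genes called in both, 2765 had the same direction. In females alone 4316 genes were called and in males alone 3359. Of the 2753 genes called in both sexes 2752 had the same direction, where 617 would be expected from independent lists.

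**Figure D2:**
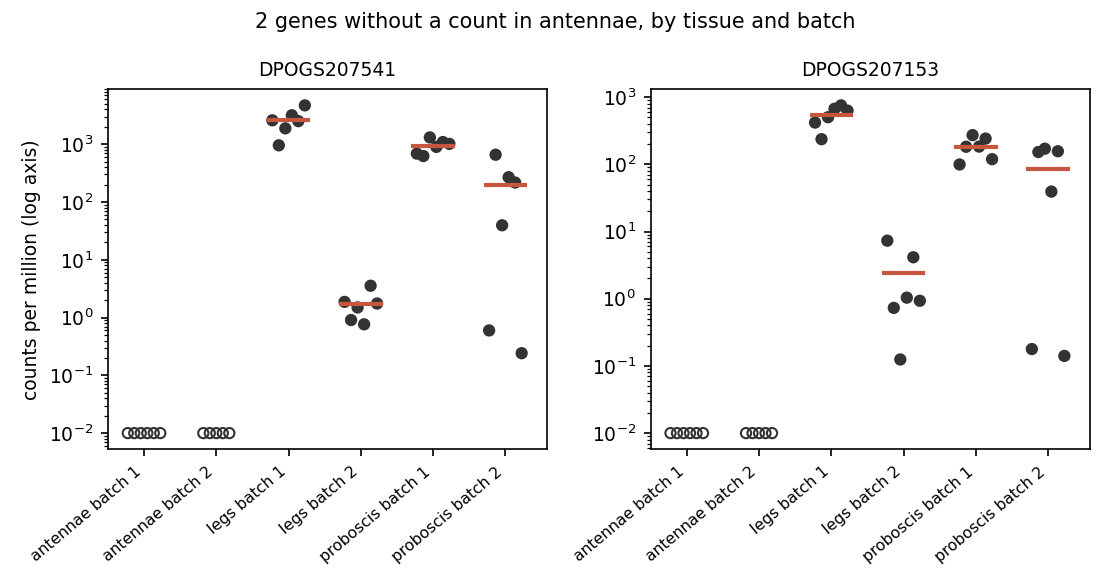
Points are single libraries and bars are group means, in CPM on a log axis, for 2 genes by tissue and batch; open points at the bottom are libraries below 0.01 CPM. DPOGS207541 and DPOGS207153 have no count in antennae, and their level in the legs of batch 2 (means of 1.72 and 2.38 CPM) lies far below that in the legs of batch 1 (2638 and 535 CPM).

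Between antennae and proboscis 3084 genes differed, 1349 higher and 1735 lower in antennae, of which 1089 and 1328 differed at least 2-fold and 172 and 318 at least 32-fold. Without the 2 libraries under 2 M counts 1136 were higher and 2130 lower, and with the others thinned to 2 M counts 1435 were higher and 1258 lower. The same 4 genes led this comparison under the naming rule. DPOGS212737 had 0.176 ± 0.268 CPM (SD, n = 12) in proboscis (log2 fold change 14.07 ± 1.11, SE, adjusted p = 6.37e-12; 14.7 without female 25). DPOGS203667 had 3 counts in all proboscis libraries together, 1 in each of 3 libraries, and its summed level was 39230 times higher in antennae (95% interval 13400 to 190000; adjusted p = 3.23e-11). The antennae of female 1 held 33039 of its 50932 antennal counts, and without that library the ratio was 18470. DPOGS207541 averaged 568 ± 458 CPM (SD, n = 12) in proboscis and was at least 10360-fold lower in antennae (adjusted p = 3.21e-06). DPOGS207153 averaged 135 ± 87.3 CPM in proboscis and was at least 3159-fold lower in antennae (adjusted p = 6.52e-06). In proboscis the batch test called neither gene (adjusted p = 0.957 for both): DPOGS207541 averaged 939 ± 258 CPM (SD, n = 6) in batch 1 and 197.5 ± 253 CPM (SD, n = 6) in batch 2 (105 CPM there without female 11), and DPOGS207153 averaged 183 ± 66.9 and 86.6 ± 81.9 CPM. The lowest proboscis libraries were those of female 1, at 0.599 and 0.178 CPM, and male 2, at 0.242 and 0.141 CPM. Computed on the proboscis libraries of batch 2 alone, the bounds were 1845-fold and 1847-fold. For DPOGS207153 the proboscis of female 3 held 5851 of the 9201 counts behind this bound. In batch 1 alone 2268 genes were called and in batch 2 alone 1815, and all 1142 genes called in both batches had the same direction. The lists of females alone (1691 genes) and males alone (1226 genes) shared 923 genes, all in the same direction, against 90.8 expected from independent lists.

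Legs and proboscis differed in 2939 genes, 1491 higher and 1448 lower in legs, of which 821 and 1185 differed at least 2-fold and 46 and 88 at least 32-fold. The split depended on the scaling and the fit: with upper-quartile scaling 1122 were higher and 1702 lower in legs, 39.7% higher instead of 50.7%. It moved the other way with the animal as a block (1891 and 1411, 57.3%), limma voom (1891 and 1297, 59.3%) and limma with the animal as a random block (2452 and 1787, 57.8%). DPOGS210455 and DPOGS210456 averaged 37.2 ± 42.04 and 33.9 ± 39.6 CPM (SD, n = 12) in legs. In proboscis each had 2 counts, both in the library of female 25, so that the summed level of DPOGS210455 was 6230 times higher in legs (95% interval 1720 to 51400; adjusted p = 9.14e-08) and that of DPOGS210456 5724 times higher (1580 to 47300; adjusted p = 1.43e-07). Their identifiers are consecutive and their levels nearly equal, and whether they share reads was not tested. Both genes were also detected in each antennal library, at 1.76 to 161 and 1.35 to 153 CPM. DPOGS209224 averaged 1.14 ± 1.66 CPM in legs and 2676 ± 2971 CPM in proboscis (log2 fold change -12.38 ± 0.91, SE, adjusted p = 2.64e-11), and it was also low in antennae, at 3.62 CPM or less in each library. DPOGS205671 averaged 0.735 ± 1.05 CPM in legs and 2350 ± 2411 CPM in proboscis (log2 fold change -12.15 ± 1.08, SE, adjusted p = 8.53e-10), with 0.782 to 1260 CPM in antennae. Every proboscis library lay above every leg library for these 2 genes. Within batch 1 the comparison called 1243 genes and within batch 2 1565, of which 657 were shared and 653 had the same direction. Females alone gave 720 genes and males alone 764, with 372 shared, all in the same direction, against 23.1 expected from independent lists. Leaving out the 10 libraries of batch 2 over 24 M counts left 1081 genes.

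**Figure D3:**
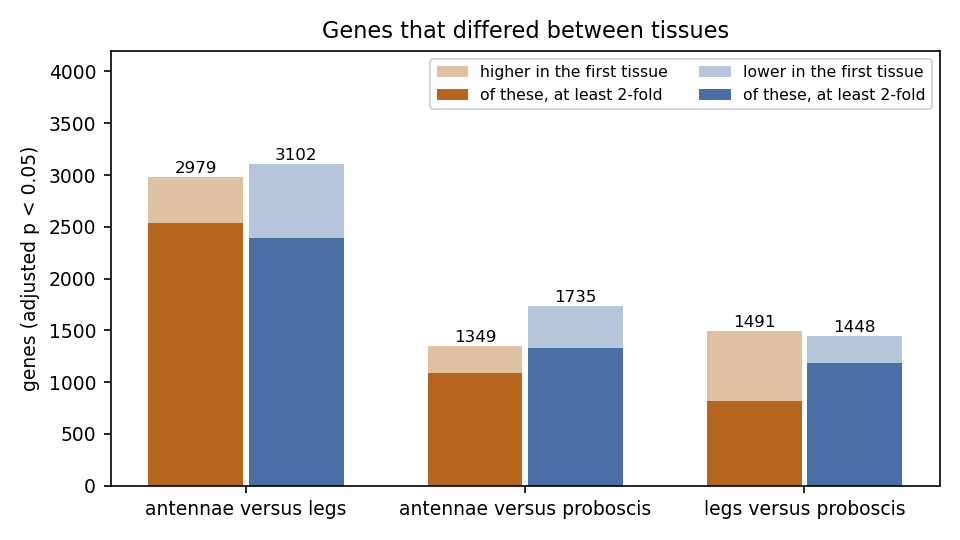
Bars give the number of genes with an adjusted p below 0.05 in each tissue comparison, split by direction in the first-named tissue, with the darker part at least 2-fold different. Antennae against legs has the tallest bars (2979 higher and 3102 lower).

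Taking the comparisons together, 6703 of the 11804 genes (56.8%) differed between at least 1 pair of tissues. Genes higher in antennae than in both other tissues numbered 1196, of which 945 were at least 2-fold and 119 at least 32-fold higher in both comparisons. Those 945 genes took 20.6% ± 3.55 (SD, n = 11) of antennal counts, 1.84% ± 0.375 (SD, n = 12) of leg counts and 3.74% ± 0.880 (SD, n = 12) of proboscis counts. Genes lower in antennae than in both others numbered 1422, and the 1029 of them that were at least 2-fold lower took 4.72% ± 0.624 of antennal counts, 50.8% ± 6.26 of leg counts and 38.8% ± 4.90 of proboscis counts. Higher in legs than in both others were 1327 genes, of which 685 passed 2-fold and 19 passed 32-fold. The 685 genes took 22.1% ± 4.74 of leg counts, 3.06% ± 0.438 of antennal counts and 9.78% ± 2.21 of proboscis counts. This leg class depended on the libraries and the fit: it held 567 genes in batch 1 alone, 431 in batch 2 alone, 482 without the batch 2 libraries over 24 M counts and 2124 with limma and the animal as a random block. Lower in legs than in both others were 1082 genes, 838 of them at least 2-fold and 28 at least 32-fold, with 457 in batch 1 alone, 849 in batch 2 alone and 399 without those deep libraries. Higher in proboscis than in both others were 268 genes, with 250 at least 2-fold and 30 at least 32-fold higher, and the 250 took 6.11% ± 2.20 of proboscis counts, 1.22% ± 0.474 of antennal counts and 0.859% ± 0.304 of leg counts. Lower in proboscis than in both others were 106 genes, 103 of them at least 2-fold and 20 at least 32-fold. The shares describe the genes chosen by these same libraries. Each class rests on 2 comparisons that share the libraries of 1 tissue. Independent lists of the same sizes would share 340.4, 455.9, 391.8, 365.4, 212.8 and 170.4 genes for the 6 classes in the order given, values that leave out the shared libraries. With the shared libraries divided between the 2 comparisons (6 and 5 antennal, 6 and 6 others), the classes held 718, 1096, 512, 290, 158 and 54 genes, against 195.3, 397.8, 136.4, 80.26, 130.5 and 58.08 from independent lists. For genes higher in proboscis the excess over independent lists was thus small, for genes lower in proboscis there was none, and part of each excess may come from the shared libraries. Both comparisons of a class also share the level of 1 tissue, so their lists are tied even with the libraries divided. No conclusion on tissue specificity is therefore drawn from an excess or its lack.

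Few genes separated the sexes. All 6 females were gravid, so sex and reproductive state were not separable. In antennae no gene was called (6 females, 5 males, edgeR), with 366 genes at an unadjusted p below 0.05 and 12 genes called by DESeq2. In proboscis no gene was called (6 females, 6 males, edgeR), with 130 genes at an unadjusted p below 0.05 and 1 gene called by DESeq2. The antennae gave 0 genes in each batch alone, and so did the proboscis. In legs 4 genes were called, 3 higher and 1 lower in females, with 733 genes at an unadjusted p below 0.05 and 68 called by DESeq2. Without any difference, a share of about 0.05 of the 11804 tested genes would lie below that unadjusted p. The numbers in antennae and proboscis were under that share, while the number in legs was above it. A number under the share means that p-values ran high there, so it cannot show whether further differences were absent.

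DPOGS209204 averaged 609 ± 672 CPM (SD, n = 6) in female legs and 6.59 ± 5.24 CPM (SD, n = 6) in male legs, a log2 fold change of 6.47 ± 0.72 (SE, adjusted p = 0.00632). Each of the 6 female leg libraries lay above each of the 6 male ones. The female leg mean was 358 CPM without female 3, and the log2 fold change was 5.76 without female 25. In antennae the gene averaged 184 ± 143 CPM in females (SD, n = 6) and 533 ± 722 CPM in males (SD, n = 5), the latter 214 ± 135 CPM without male 16. In proboscis it ranged from 0.162 to 25.4 CPM in females and from 0 to 0.705 CPM in males. DPOGS208131 averaged 481 ± 283 CPM in female legs and 46.0 ± 22.2 CPM in male legs (log2 fold change 3.27 ± 0.45, SE, adjusted p = 0.0225), again without overlap between the sexes. Its level was 13.9 to 161 CPM in female and 7.77 to 30.7 CPM in male proboscis and at most 8.81 CPM in any antennal library. The gene lower in females, DPOGS203388, averaged 0.0237 ± 0.050 CPM in female legs and 1.61 ± 1.37 CPM in male legs (log2 fold change -6.04 ± 0.90, SE, adjusted p = 0.0384). It had a count in all 6 male leg libraries and in 2 of the 6 female ones, with 408 and 5 counts. The means were 1.06 CPM in male legs without male 2 and 0.00352 CPM in female legs without female 3, and without female 3 the log2 fold change was -7.65. Over all tissues 14 of 17 male libraries had a count of it, 909 counts in all, and 2 of 18 female libraries, with 5 counts in 409 M.

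Leaving out 1 animal at a time ended some leg calls, while the log2 fold changes kept their direction, at 5.76 to 6.68 for DPOGS209204, 3.09 to 3.48 for DPOGS208131 and -7.65 to -5.53 for DPOGS203388. Without male 2 no gene was called, without male 12 there were 2, and without male 15, male 16 or female 25 there was 1 each. Batch 1 alone called 2 genes, neither of them among the 4, and batch 2 alone called 0. DPOGS209204 kept its call in 11 of the 12 fits that left out 1 animal (adjusted p = 0.0537 without male 2), DPOGS208131 in 6 (lost without male 2, 12, 15 or 16 or female 25 or 27) and DPOGS203388 in 1 (kept without female 3). Without the batch term all 3 lost their calls (adjusted p = 0.0936, 0.0996 and 0.145, in the order given), and with all libraries in 1 fit DPOGS208131 and DPOGS203388 did (adjusted p = 0.0623 and 0.354). A sex difference that depended on the tissue was called for 1 gene, DPOGS209204 (interaction test of edgeR, adjusted p = 0.0264, 318 genes at an unadjusted p below 0.05), and 5 genes were called by DESeq2. The 318 genes were under the share of 0.05 that would arise without any difference. The test left out the pairing by animal and recovered 26% of 4-fold changes in simulated data. The low number therefore does not show that such differences were absent. With the animal as a block the interaction called 0 genes, and it also called 0 without female 1, 11, 25 or 27 or male 15, 16 or 20.

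**Figure D4:**
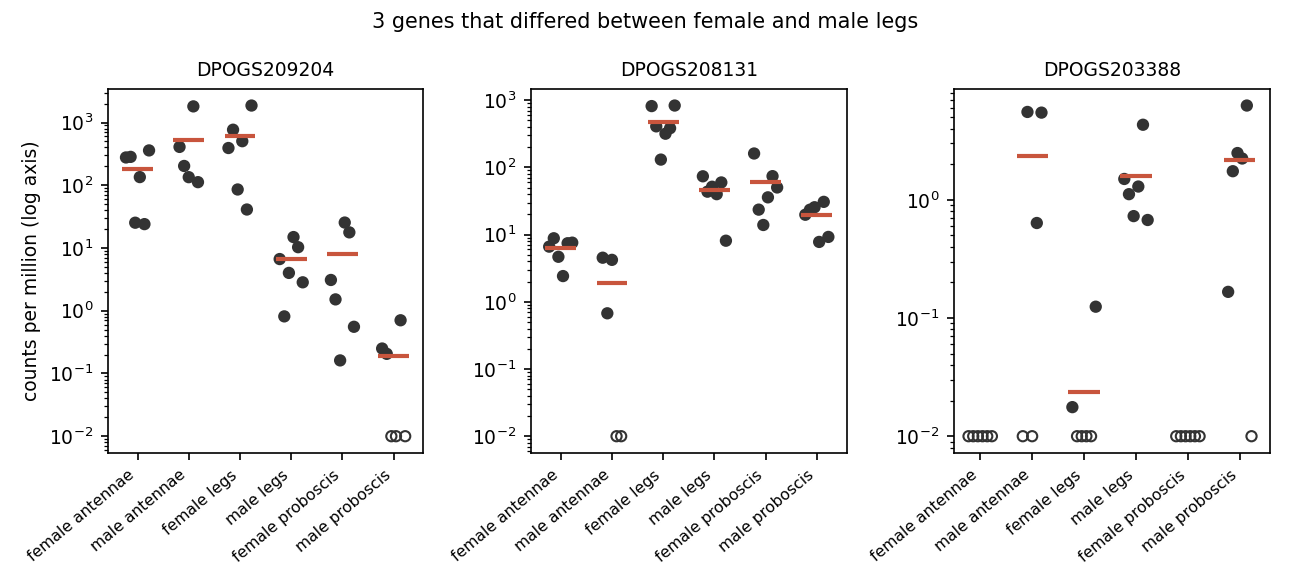
Points are single libraries and bars are group means, in CPM on a log axis, for the 3 named genes that differed between female and male legs; open points at the bottom are libraries below 0.01 CPM. For DPOGS209204 and DPOGS208131 the 6 female leg libraries lie above the 6 male ones, and DPOGS203388 has a count in 2 female libraries, both from legs.

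The batches differed most in legs. Between batch 2 and batch 1, 4873 genes differed in legs, 2407 higher and 2466 lower in batch 2, with 1419 and 2155 at least 2-fold different and 5 and 205 at least 32-fold different. In antennae 1 gene differed between batches (838 at an unadjusted p below 0.05, 103 called by DESeq2) and in proboscis 0 (471 at an unadjusted p below 0.05, 16 called by DESeq2). The 471 genes were under the share of 0.05 that would arise without any difference, and the 838 were above it. The proboscis libraries of batch 2 varied widely on the first principal component (SD 52.9, n = 6, against 11.2 in batch 1, n = 6). The low number in proboscis therefore does not show that the batches were alike there. A batch difference that depended on the tissue was called for 914 genes in a fit with a batch term for each tissue. Each batch held 3 females and 3 males and all 3 tissues, so neither sex nor tissue was tied to the batch.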

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

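The tests of the leg batch difference, of power, of the female leg gene and of regrouped labels were chosen after the results had been seen.

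The batch difference in legs was flagged because it depended on the tissue, with 914 genes in the test of batch by tissue. The 205 genes at least 32-fold lower in the legs of batch 2 had a median of 6.44 to 8.69 CPM in the 6 leg libraries of batch 1 and 0 to 0.167 CPM in those of batch 2. A score per library, the mean log2 CPM of the 1419 genes higher in batch 2 legs minus that of the 2155 genes lower there, was -0.54 ± 0.18 (SD, n = 6) in the proboscis of batch 1. In batch 2 proboscis it was over 10 such SDs above that mean in 2 of 6 libraries (4.37 in male 2 and 2.80 in female 1) and below each batch 1 library in 2 others (-1.68 in female 11 and -1.08 in male 12).

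Sampling depth alone does not account for this difference, since with every leg library thinned to 2 M counts 3817 genes were still called between the leg batches. A state of the whole animal that moved the genes of the score alike in legs and proboscis is argued against in 2 batch 2 animals. Their proboscis scored below the batch 1 mean while their legs scored 3.69 and 2.92. For 1 of them, female 11, the proboscis library held 1.92 M counts. Both tissues scored high in male 2 (4.53 in legs and 4.37 in proboscis) and female 1 (2.34 and 2.80), so such a state stays open there. The genes of the score were chosen in legs, so a state that acted on other genes in proboscis was not tested. Library preparation or RNA quality that went with a high total count is a candidate explanation: over the 6 batch 2 proboscis libraries the score rose with the log10 total count (Spearman rho = 0.943, exact permutation p = 0.0167, adjusted over 2 relations 0.0334; Pearson r = 0.779, exact permutation p = 0.0542, adjusted 0.108; r = 0.820 without the 2 libraries farthest from the median total). Over the 6 batch 2 leg libraries, all above 35 M counts, no such relation was seen (rho = 0.0857, exact permutation p = 0.919, adjusted 0.919; r = -0.121, exact permutation p = 0.800, adjusted 0.800; r = -0.674 without the 2 farthest). GC content and gene length were not tested and stay open.

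Few sex differences were called in antennae and proboscis. Limited power may contribute, since the simulated data recovered 18% of 4-fold changes in antennae and 32% in proboscis. In legs 74% of 4-fold changes were recovered, but the simulated leg comparison called 133 genes and the real one 4. With fewer calls the adjustment asks for a smaller unadjusted p, so the 74% does not measure the power when few genes differ. It argues only against a set of 4-fold changes as large as the simulated one having been missed. A lack of power for a few 4-fold changes, and for smaller differences, stays open in legs. Other splits of the animals by sex within batches say nothing about the counts of 0 in antennae and proboscis, which each of the 40 splits must equal or exceed (highest other 0 in both). In legs 1 of 40 splits, the real one, gave 4 genes and the highest other gave 0. This is the smallest share that 40 splits can give. It argues against chance, but since no gene was called in legs without male 2, chance is not excluded.

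DPOGS209204 was flagged because its sex difference depended on the tissue (adjusted p = 0.0264). RNA carried over from antennae into the female leg libraries would leave a small percentage of the antennal level, but the female legs held at least 141.4% of the level in the antennae of the same female, in 6 of 6 females, and the antennal gene DPOGS212737 stayed at or below 0.436 CPM in female legs. Male legs held 1.24% of the mean male antennal level, or 3.07% without the antennae of male 16. Reads shared with a near-identical gene, and a state tied to egg laying in these gravid females, were not tested and stay open. Regrouping the sexes gave as many interaction genes in 5 of 40 splits (real 1, highest other 2), so chance is not excluded for the interaction.

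Of 36 groups of values tested for a library far from the rest of its group, 8 were flagged. The limits used hold for normally distributed values, and skewed totals and CPM values can pass them more often. The number that chance would flag is therefore not known. Total counts were farthest from the rest for the legs of male 12 (117 M, next 50.7 M) and the proboscis of male 2 (41.8 M, next 19.2 M). The proboscis of female 11, with 1.92 M counts, had 8610 genes in a draw of 600000 counts (next 9819). The 10 most abundant genes took 25.7% of the counts in the proboscis of male 20 (next 18.9%). DPOGS209204 reached 1807 CPM in the antennae of male 16 (next 408 CPM) and 0.705 CPM in the proboscis of male 2 (next 0.250 CPM). DPOGS203388 reached 0.125 CPM in the legs of female 3 (next 0.0176 CPM) and 4.32 CPM in the legs of male 2 (next 1.502 CPM).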

How the results depend on the processing

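Not counting fits without 1 animal, 205 of 263 alternative counts lay within 1.5 times of the main count. Of 451 alternative fits of the named genes, here with the fits without 1 animal, 420 stayed past the threshold in the same direction, 31 kept the direction but missed the threshold and 0 reversed. Most misses were of the sex differences in legs: 4 of 27 fits for DPOGS209204, 10 of 27 for DPOGS208131 and 15 of 25 for DPOGS203388. Among the tissue differences DPOGS207541 and DPOGS207153 missed between antennae and legs, each in 1 of 31 fits (batch 2 alone). The cause of the changes below was not tested, except that fits on 1 sex, 1 batch or fewer libraries have fewer samples. Fits on thinned counts, with 1 surrogate variable, without deep or shallow libraries, with a batch term per tissue, and all alternatives for the tissue classes and the batch comparisons were chosen after seeing the data. Gene list alternatives, and the sex comparisons without ovary and fat body genes, were not run because no identifier had a name.

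In females alone and males alone the counts were 1691 and 1226 between antennae and proboscis and 720 and 764 between legs and proboscis, and males alone gave 3359 between antennae and legs. Batch 1 alone gave 1243 between legs and proboscis, and batch 2 alone gave 1565 there and 1815 between antennae and proboscis. Without the batch 2 libraries over 24 M counts the leg against proboscis count was 1081. Genes higher in antennae than in both others numbered 753 and 478 in batch 1 and batch 2 alone, 624 in females and 394 in males; genes lower in antennae numbered 811 in females and 633 in males. Genes higher in legs numbered 567 and 431 in the batches, 287 and 402 in the sexes, 482 without the deep batch 2 libraries and 2124 with limma and the animal as a random block (consensus correlation 0.266). Genes lower in legs numbered 457 in batch 1 alone, 268 in females, 205 in males and 399 without the deep batch 2 libraries. Genes higher in proboscis numbered 103 and 115 in the batches, 70 and 71 in the sexes and 114 without the deep batch 2 libraries, and genes lower there 42 and 57, 36 and 34, and 48, with 68 after thinning.

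Among sex comparisons, DESeq2 called 12 genes in antennae, 68 in legs and 1 in proboscis, and all libraries in 1 fit gave 4 in antennae and 1 in legs. In legs limma voom gave 7, voom with quality weights 16, 1 surrogate variable 13, no batch term 1, batch 1 alone 2, batch 2 alone 0, and thinning to 2 M counts 2. The deep batch 2 libraries include all 6 batch 2 leg libraries, so leaving them out repeats the batch 1 fit there (2 genes, counted once above). The interaction gave 5 genes with DESeq2, 2 with 1 surrogate variable and 0 with limma voom, no batch term, the animal as a random block or without the deep batch 2 libraries. With the replicate block (the animal number) the interaction gave 0 genes, and the tissue counts, 5988, 3119 and 3302, stayed within 1.5 times. The batch comparison in antennae gave 103 genes with DESeq2 and 4 with limma voom, and that in proboscis 16 with DESeq2.

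Leaving out each animal in turn, the counts ran from 5467 to 6139 between antennae and legs, 2693 to 3166 between antennae and proboscis, 2213 to 2941 between legs and proboscis, 0 to 4 for sex in legs (0 without male 2) and 0 to 1 for the interaction (0 without animals 1, 11, 15, 16, 20, 25 or 27). Upper-quartile scaling moved the median log2 fold change of all genes by 0.196 between antennae and legs and by -0.122 between legs and proboscis, and DESeq2 size factors moved the former by 0.102. Of the 4 libraries under 3 M counts, 3 were antennal and 1 was from proboscis.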

Other observations

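DPOGS203388 was counted almost only in males. It had a count in 6 of 6 male leg libraries and in 14 of 17 male libraries, against 2 of 18 female libraries, and it was at 0 to 5.54 CPM in male antennae and 0 to 6.28 CPM in male proboscis, with 0 counts in the antennae and proboscis of the 6 females. Neither of the latter differences was called. Of the 205 genes that were at least 32-fold lower in the legs of batch 2, 133 showed no tissue difference called among the libraries of batch 1. Batch 1 alone called 4480, 2268 and 1243 of the 11804 genes in the 3 tissue comparisons, so other genes lacked a call too. The share without a call over all genes was not computed, so the 133 are not shown to set these genes apart.

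For the tissue comparisons, labels exchanged within animals were used as other splits, a test chosen after the results had been seen. In each, 1 of 40 splits (the real one) gave as many genes: 6081 against a highest other of 311 between antennae and legs, 3084 against 2669 between antennae and proboscis, and 2939 against 86 between legs and proboscis. This argues against chance at that level, the smallest that 40 splits can give. The split that gave 2669 genes points to a structure of the samples: it put the antennal label on 8 antennal libraries and the proboscis label on 10 leg libraries, so it was largely an antennae against legs comparison. For the batches, labels exchanged between animals gave as many genes in 3 of 40 splits in antennae (real 1, highest other 8), which does not exclude chance. In legs 1 of 40 did (real 4873, highest other 0), which argues against chance at that level. In proboscis the count of 0 is met by each of the 40 splits (highest other 0), so this test has no bearing there.

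Genes with consecutive identifier numbers may share their tissue class more often than chance, a test written before its result was seen. Among 9347 pairs of tested genes whose numbers differ by 1, 428 pairs had both members in the same class of genes higher in 1 tissue, 181 of them in the antennal, 214 in the leg and 33 in the proboscis class. In 1000 shuffles of the classes over the genes the mean was 217.7 and the highest 259, so a chance order of the identifiers is argued against. What consecutive numbers mean on the genome was not used here, and gene copies that share reads, or 1 gene divided into 2 models, were not tested.

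A hypothesis that legs and proboscis share sex differences too small for either tissue was tested on counts summed over the 2 tissues of each animal (6 females, 6 males), a test also written before its result was seen. It called 3 genes (edgeR, smallest adjusted p 0.00271), with 403 at an unadjusted p below 0.05, under the share of 0.05 that would arise without any difference. All 3 were among the 4 genes called in legs, so the test missed the bound of more than 4 genes set beforehand. A simulation added after that result leaves the hypothesis open, since the summed test (11802 genes) recovered 4% of 2-fold and 74% of 4-fold changes. In the real data legs held 89.8% and 97.5% of the summed counts in male 12 and female 11 (median over the 12 animals 55.7%).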
